A study of Mus musculus with 6 samples.

How the data were processed

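The series holds 6 Affymetrix Mouse Gene 1.0 ST arrays of heart ventricle RNA from 3.5-week-old male mice, 3 labelled as lacking Hspa4 and 3 labelled wild type. Per the labels' protocols, total RNA was extracted with Trizol, and cDNA was made and labelled with biotin with the Affymetrix WT Target Labeling Kit. There were 3 mice for each genotype, so each array was taken to be a separate mouse. The deposited values are on the log2 scale, 1 for each probe set and array, and the authors made them with R 2.13.0 and the affy package, per the submitters' processing notes. The background correction, the normalisation between arrays and the summary method are not given in the sources used here. The array columns do not share 1 distribution: their SDs run from 1.19 to 1.27 with medians from 6.42 to 6.48. The values were kept as deposited for the main tests. The table gave no measure of background, so signal over background is unknown, and the number of arrays limits the precision.

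Probe sets were named through the probe annotation table for the array. Of 21225 probe sets, 20239 carried 1 gene symbol, 0 carried several and 986 carried none. The gene number of each of the 20239 was found in a RefSeq gene table of the assembly GRCm38.p6, and 0 symbols needed an update. That table served only for names and for which genes neighbour each other. Each symbol had 1 probe set, so the planned mean over several probe sets of a gene changed nothing and was not run. The planned pseudocounts were for linear values and were not run either, since the values were already log2. All value columns of the table belonged to the 6 arrays. Pairs of arrays shared from 11 to 30 identical values of 21225, so no array was a copy of another.

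Groups came from the labels alone. The comparison between groups was a 2-group model in limma 3.58.1 (lmFit and eBayes, R 4.3.3) over 20239 genes, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. No filter on low values was applied in the main test. Hspa4 was also tested with an exact two-sided permutation test. The model, the gene lists, the rule for named genes and the alternatives were fixed before the data were examined. Differences are the mean of the arrays labelled Hspa4-/- minus the wild-type mean, with limma's moderated SE, and a fold is taken from the difference of log2 means.

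Hspa4 on the array labelled Hspa4-/- replicate 1 goes against its label, so it is called by its label throughout. Leaving out each array in turn was planned. The fuller description of the 5 arrays left without that array, and the alternatives on those 5 arrays, were added after its Hspa4 and Xist values were seen. Genes were also described by whether the 2 groups' values overlap, where chance gives 10% of genes without overlap for 3 against 3 and 20% for 2 against 3.

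The 35 gene lists, 22 of pathways and 13 of cell type markers, were written from general knowledge of the heart and of other cells a ventricle sample could hold. The pathway lists were hypertrophy genes raised in stressed hearts, adult cardiac genes lowered in stressed hearts, extracellular matrix and fibrosis, the Hsp70 and Hsp110 family without Hspa4, cytosolic co-chaperones and heat shock response, the unfolded protein response, proteasome subunits, muscle ubiquitin ligases and autophagy, calcium handling, sarcomere and Z disc, fatty acid oxidation, oxidative phosphorylation, glycolysis, cell cycle, p53 targets, oxidative stress, interleukin 6 response, type I interferon response, cholesterol and fatty acid synthesis, circadian clock, immediate early genes and hypoxia. The marker lists covered fibroblasts, myofibroblasts, endothelial cells, smooth muscle cells and pericytes, macrophages and monocytes, lymphocytes and neutrophils, erythroid cells, atrial and conduction cells, adipocytes, mesothelium, Schwann cells and neurons, skeletal muscle, and lung and thymus. Lists were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over the 35 lists. The tests were repeated with an estimated correlation and with fry, limma's rotation test. List members not found among the named probe sets were not analysed here. For each list the members were also adjusted over the list alone.

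Named genes were chosen by rule. The rule took Hspa4 and the 12 genes with the largest difference in each direction among those past the threshold without overlap between groups. Where fewer than 5 passed in a direction, it took the 8 with the smallest p. It also took up to 4 members of each list that passed over the list alone, or up to 2 with the smallest p, and Nppa, Nppb, Myh7, Myh6, Acta1, Col1a1, Col3a1, Hspa4l, Hsph1, Hspa8 and Rcan1. Predicted genes and genes with clone names were counted but not named. Genes within 10 Mb of Hspa4 were set against 10000 random gene sets matched on mean expression.

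The alternatives were filters leaving out the lowest 25% or 50% of genes by mean value, quantile normalisation, subtraction of array medians, eBayes with trend and robust settings, array weights, the replicate number as a block, all probe sets, a 1.5-fold threshold, and leaving out each array in turn. For lists, camera on ranks was a further alternative. The tests were checked on simulated data on the same 20239 genes with 50 genes changed at each size. For 3 against 3 arrays 44 of 50 were recovered at a log2 change of 0.5 and 50 of 50 at changes of 1, 2 and 3, with 16 false calls. For 2 against 3 arrays 48 of 50 were recovered at 0.5 and 50 of 50 at the larger changes, with 16 false calls. A list shifted by 0.3 was recovered in both, with 0 false lists. The simulated noise was independent between genes, so this check says nothing about false lists where genes vary together, as on real arrays. With many genes changed at once, the adjusted threshold is also easier to reach than where few or none pass. The recovered shares therefore do not give the power of the real comparison. On the real 6 arrays Chordc1, with a log2 difference of −0.77, did not pass.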

Results

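Total RNA from the heart ventricles of 3.5-week-old male mice was hybridised to Affymetrix Mouse Gene 1.0 ST arrays, which read each transcript with probes spread along its length. The labels put 3 arrays in a group lacking Hspa4 (Hspa4-/-) and 3 in a wild-type group (Hspa4+/+). Each array was taken to be a separate mouse. The deposited table held 21225 probe sets, of which 20239 carried 1 gene symbol and were tested. Array means lay between 6.76 and 6.77 and array medians between 6.42 and 6.48 on the log2 scale. The number of arrays limits the precision. The comparison asks which genes of the young heart differ when Hspa4 is lost.

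Hspa4, which encodes a cytosolic chaperone of the Hsp110 family that exchanges nucleotide on Hsp70, was low on only 2 of the 3 arrays labelled Hspa4-/-. Its log2 value was 6.63 and 6.75 on the arrays labelled Hspa4-/- replicates 2 and 3. The wild-type arrays read 9.74, 9.50 and 9.48. The array labelled Hspa4-/- replicate 1 read 9.33, a difference of −0.24 from the wild-type mean, so its Hspa4 level goes against its label. Over all 6 arrays Hspa4 was 7.57 ± 1.53 (SD, n = 3) on the arrays labelled Hspa4-/- and 9.57 ± 0.15 (SD, n = 3) in wild type. The difference of −2.01 (SE 0.58) did not pass (limma, adjusted p = 0.263), and the exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 arrays can give. With the array labelled Hspa4-/- replicate 1 left out, Hspa4 was 7.40-fold lower (log2 difference −2.89, SE 0.10, n = 2 against 3; limma, adjusted p = 9.37e-06). That array was set aside for its Hspa4 level, so this last value is not independent evidence for Hspa4. Which part of the gene was disrupted is not given in the sources used here.

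Xist, the noncoding RNA that coats the inactive X chromosome of female cells, also set the array labelled Hspa4-/- replicate 1 apart. It read 7.68 there and between 5.51 and 5.69 on the other 5 arrays, although every array is labelled male. Its level on that array was 4.16-fold the mean of the others. The Y-linked genes Eif2s3y and Uty, expressed in male cells, were lower there but still high. Eif2s3y read 7.96 against 8.23 to 8.39 on the other 5 arrays, which is 76.8% of their mean on the linear scale. Uty stood at 75% of that mean and the Y-linked Kdm5d at 93.3%, the latter within the range of the other arrays. The array was kept in its labelled group for the main comparison, and each count was also computed without it.

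**Figure D1:**
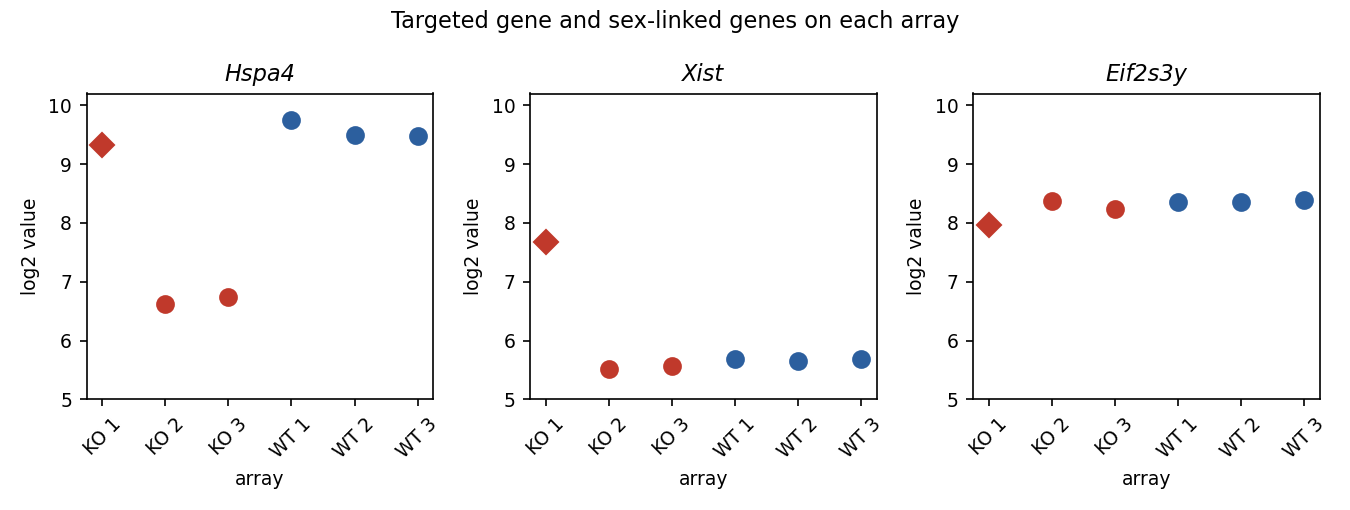
Log2 values of Hspa4, Xist and Eif2s3y on each of the 6 arrays, 1 point per array, with the array labelled Hspa4-/- replicate 1 (KO 1) as a diamond. KO 1 read 9.33 for Hspa4, near the wild-type arrays, and 7.68 for Xist, above the other 5 arrays at 5.51 to 5.69, while Eif2s3y at 7.96 lay a little below them.

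With all 6 arrays, Chordc1 and Leng8 had the smallest p of all genes, and no gene passed the threshold. Chordc1, a co-chaperone that binds Hsp90, had a log2 difference of −0.77 (SE 0.08, n = 3 per group) between the arrays labelled Hspa4-/- and wild type. Leng8 had a difference of 0.72 (SE 0.08). Both had an adjusted p of 0.0773 (limma, Benjamini-Hochberg), and on both genes the array labelled Hspa4-/- replicate 1 lay with the other arrays of its label. Among genes with higher values and the next smallest p were Nrbp2 (0.55), Rnf207 (0.55), Adamtsl4 (0.48), Pdzd2 (0.43), Cdc42ep1 (0.43), Grk3 (0.36) and Sun2 (0.34). Among genes with lower values were Tbc1d8b (−0.68), Ptp4a1 (−0.65), Alkbh8 (−0.59), the complement gene C7 (−0.54), the potassium channel gene Kcnd2 (−0.53), Mrgprh (−0.52) and the collagen prolyl hydroxylase gene P4ha1 (−0.51). Their adjusted p lay between 0.189 and 0.210 (limma), so none of them passed.

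The cardiac stress gene Nppa, which encodes atrial natriuretic peptide, had a log2 difference of 1.79 (SE 0.40; limma, adjusted p = 0.213) with all 6 arrays. It was 10.48 ± 1.03 (SD, n = 3) on the arrays labelled Hspa4-/- and 8.69 ± 0.23 (SD, n = 3) in wild type. The array labelled Hspa4-/- replicate 1 stood at 9.43, above every wild-type array and below both others of its label. Of 20239 genes, 0 had an adjusted p under 0.05 (limma), while 2261 had an unadjusted p under 0.05, 1141 of them higher and 1120 lower, where chance gives 1012. That excess cannot be tied to the labels, since setting the array labelled Hspa4-/- replicate 1 and wild-type replicates 1 and 3 against the other 3 arrays gave 2941. In 3066 genes, or 15.1%, the values of the 2 groups did not overlap, where chance gives 10%. A low-value filter let Chordc1 and Leng8 pass, and limma's array weights gave 115 genes. Without the array labelled Hspa4-/- replicate 1 the count was 89 genes, and without wild-type replicate 2 it was 112, while leaving out any of the other arrays gave 0.

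Nppa, once the array labelled Hspa4-/- replicate 1 was left out, was 4.99-fold higher on the 2 other arrays labelled Hspa4-/- than on the 3 wild-type arrays (log2 difference 2.32, SE 0.24; limma, adjusted p = 0.0127). Kcne1, an accessory subunit of potassium channels, rose 2.77-fold (SE 0.09 on the log2 scale; limma, adjusted p = 8.87e-04). Skeletal alpha-actin, Acta1, rose 2.50-fold (SE 0.18; limma, adjusted p = 0.0310). Mylk4, a kinase of the myosin light chain kinase family, fell 3.25-fold (SE 0.15; limma, adjusted p = 0.00706). Monoamine oxidase B, Maob, fell 2.88-fold (SE 0.10; limma, adjusted p = 0.00107).

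Other genes that rose without that array were the regulatory myosin light chain gene Myl9 (2.30-fold), Dpysl3 (2.12-fold), the LIM-domain gene Fhl1 (2.04-fold), the calsequestrin gene Casq1 (2.03-fold), the G protein subunit gene Gnao1 (1.92-fold), Rasd2 (1.88-fold), Igfbp3 (1.75-fold), the cardiac ankyrin repeat gene Ankrd1 (1.68-fold) and Perp (1.66-fold). Genes that fell were Lgi1 (2.46-fold), the prolyl hydroxylase gene Egln3 (2.08-fold), the neprilysin gene Mme (2.04-fold), Upk1b (1.87-fold), Cetn4 (1.85-fold), Fam81a (1.83-fold), Chordc1 (1.77-fold) and Abhd18 (1.75-fold). Hsph1, the stress-inducible relative of Hspa4, fell by 1.00 on the log2 scale (SE 0.08; limma, adjusted p = 0.00334). The adjusted p of the genes in this paragraph lay at or under 0.0442 (limma).

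In all, 89 genes passed the threshold without the array labelled Hspa4-/- replicate 1, 47 higher and 42 lower, and 55 of them differed by at least 1.5-fold (limma, 20239 genes). Setting wild-type replicates 1 and 3 against the rest of these 5 arrays, which mixes the labels, gave 85 genes. That split also had more genes at an unadjusted p under 0.05, 3641 against 3018 (limma). The count alone therefore does not tie these genes to the labels. The values of the 2 groups did not overlap in any of the 89, and over all genes 33.3% did not overlap, where chance gives 20% for 2 against 3. The array left out took no part in choosing the 88 genes other than Hspa4, but the 3 wild-type arrays it is set against did, which alone favours agreement. Its lying on the side of the other arrays labelled Hspa4-/- of the wild-type mean in 75 of them is therefore no independent support. It lay as far as the nearer of those arrays in 2. Nppa stood 0.75 above the wild-type mean on it, Chordc1 differed by −0.66 and Mylk4 by −0.51, while Kcne1 differed by 0.12 and Casq1 by −0.16. The count of 89 rested on few arrays: it was 25 and 19 without the arrays labelled Hspa4-/- replicates 2 and 3, and 6, 875 and 2 without wild-type replicates 1, 2 and 3. Subtracting array medians gave 36 genes and array weights gave 321, and the balance of directions moved too, from 635 higher and 240 lower without wild-type replicate 2 to 43 higher and 51 lower with quantile normalisation and 16 higher and 20 lower with subtracted medians, while Hspa4 and Kcne1 passed in every setting.

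**Figure D2:**
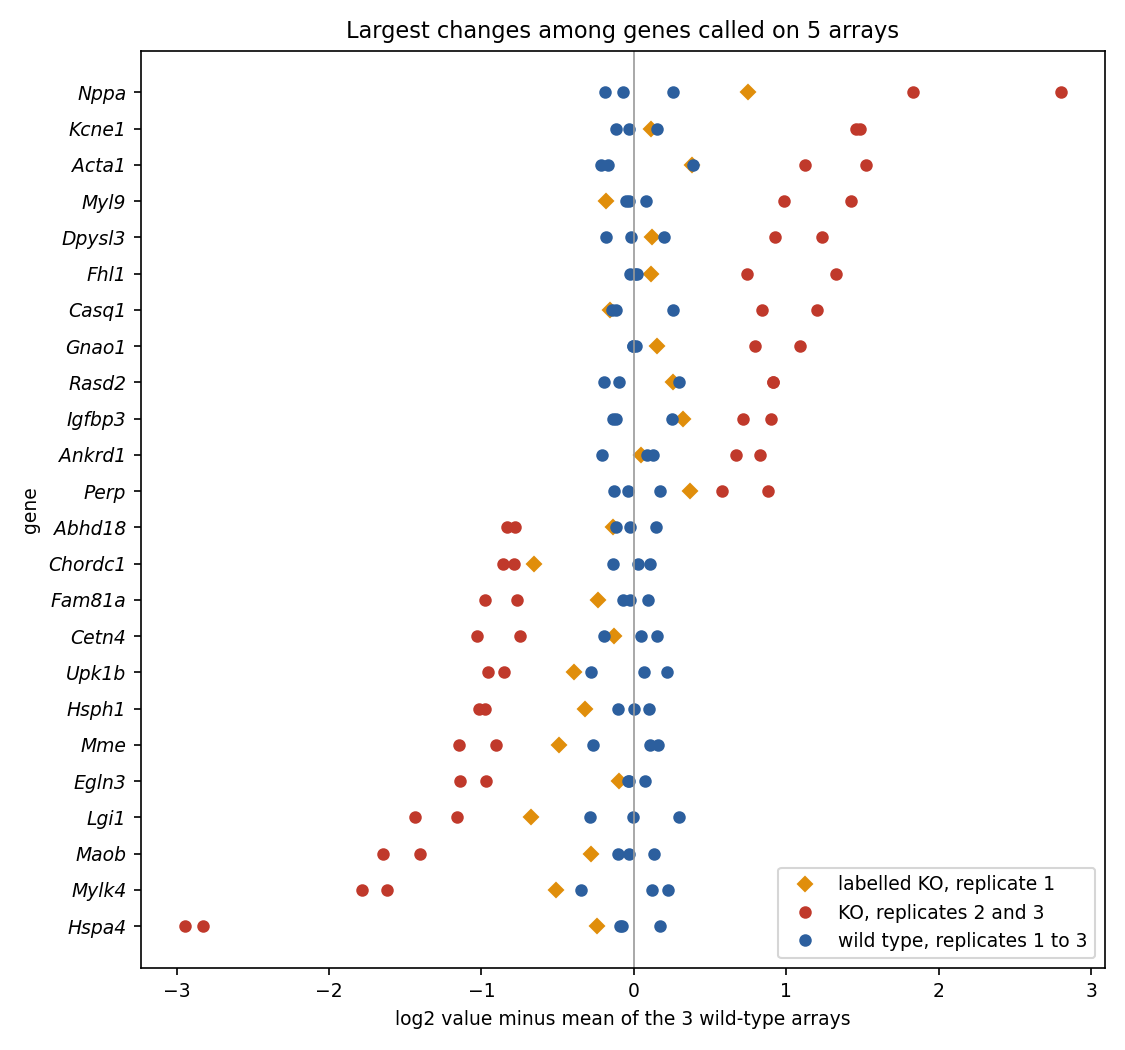
Log2 value minus the mean of the 3 wild-type arrays for the 12 genes with the largest rise and the 12 with the largest fall among the 89 genes called on 5 arrays, 1 point per array. The array labelled Hspa4-/- replicate 1 (diamond, not used in the test) lies between wild type and the other arrays labelled Hspa4-/- for genes such as Nppa, Chordc1 and Mylk4, and with wild type for Kcne1 and Casq1.

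Genes known to be raised in stressed hearts were higher together in both forms of the comparison, which share 5 arrays and are not independent. Splits of the arrays that mix the labels gave up to 13 passing lists on 6 arrays and 16 on 5, against 11 and 14 here. A camera call alone therefore does not tie a list to the labels. With all 6 arrays, 0 of the 19 measured genes passed over all genes and 13 passed adjusted over the list alone, each of them higher. Their median log2 difference was 0.35 (limma camera, adjusted p = 1.51e-09, or adjusted p = 0.335 with an estimated correlation). Nppb, the gene of brain natriuretic peptide, differed by 0.50 (SE 0.11), the beta-myosin heavy chain gene Myh7 by 0.58 (SE 0.14) and Acta1 by 1.01 (SE 0.26). On the 5 arrays left without the array labelled Hspa4-/- replicate 1, Nppa, Acta1, Fhl1 and Ankrd1 rose over all genes and 13 adjusted over the list alone, with a median of 0.39 (camera, adjusted p = 1.83e-11, or adjusted p = 0.293 with an estimated correlation). Nppb at 0.60 (limma, adjusted p = 0.0520) and Myh7 at 0.70 (limma, adjusted p = 0.0623) did not pass over all genes. The alpha-myosin gene Myh6 differed by 0.09 (limma, adjusted p = 0.631) and the calcineurin target Rcan1 by 0.04 (limma, adjusted p = 0.869). Direction on 6 arrays includes the array whose Hspa4 level goes against its label, on which the list's median difference from wild type was 0.12.

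Sarcomere and Z-disc genes were also higher as a list. With all 6 arrays 8 of 30 passed adjusted over the list alone and 0 over all genes, and the median was 0.23 (camera, adjusted p = 2.52e-10, or adjusted p = 0.335 with an estimated correlation). The Z-disc gene Ldb3 (0.41), the slow skeletal troponin I gene Tnni1 (0.40) and the desmin gene Des (0.46) were among the 8. On 5 arrays Acta1, Smpx (log2 difference 0.70, SE 0.07) and Tnni1 (0.47, SE 0.07) rose over all genes. Adjusted over the list alone 16 rose, among them the titin-cap gene Tcap (0.55, SE 0.10), and the median was 0.28 (camera, adjusted p = 1.37e-12, or adjusted p = 0.138 with an estimated correlation). This was the only list that passed limma's rotation test fry (adjusted p = 0.0301), which asks whether its genes moved one way. On 6 arrays the median fell to 0.13 without the array labelled Hspa4-/- replicate 2, and the camera call held.

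Extracellular matrix and fibrosis genes shifted upward by a smaller amount. With all 6 arrays 0 of 35 passed on either count, and the median was 0.07 (camera, adjusted p = 0.00149, or adjusted p = 0.515 with an estimated correlation). The basement membrane collagen gene Col4a1 differed by 0.39 (SE 0.11) and the lysyl oxidase gene Lox by 0.32 (SE 0.08). On 5 arrays 0 passed over all genes and 9 rose adjusted over the list alone, with a median of 0.09 (camera, adjusted p = 7.71e-06, or adjusted p = 0.504 with an estimated correlation). Examples were the periostin gene Postn (0.42, SE 0.09), Thbs4 (0.40, SE 0.08), Sparc (0.39, SE 0.07) and Tgfb2 (0.37, SE 0.07). The main fibrillar collagens did not pass on 5 arrays: Col1a1 differed by 0.31 (SE 0.14; limma, adjusted p = 0.358) and Col3a1 by 0.14 (SE 0.14; limma, adjusted p = 0.701). Without the array labelled Hspa4-/- replicate 3 the median fell to 0.02 on 6 arrays and 0.03 on 5, and the camera call was lost in both forms (adjusted p = 0.381 and 0.142). The median rose to 0.11 on 6 arrays without wild-type replicate 1 and to 0.24 on 5 without the array labelled Hspa4-/- replicate 2.

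In the Hsp70 and Hsp110 family, 10 of 13 genes were lower with 6 arrays and 8 of 13 with 5. Here 0 of the 13 passed over all genes with 6 arrays, and adjusted over the list alone 4 were lower and 1 higher. Hspa13 differed by −0.41 (SE 0.07), Hsph1 by −0.77 (SE 0.16), Hspa4l by −0.25 (SE 0.08), the endoplasmic reticulum chaperone Hspa5 by −0.39 (SE 0.13) and Hspa12b, named after its values were seen, by 0.24 (SE 0.08). The family did not pass as a list (camera, adjusted p = 0.0629). On 5 arrays Hsph1 fell over all genes, and Hsph1, Hspa13 and Hspa5 fell adjusted over the list alone (camera, adjusted p = 0.0734). On those 5 arrays Hspa4l differed by −0.24 (SE 0.08; limma, adjusted p = 0.246) and the constitutive Hsp70 gene Hspa8 by −0.18 (SE 0.10; limma, adjusted p = 0.474). Low-value filters, quantile normalisation and leaving out the array labelled Hspa4-/- replicate 3 or wild-type replicate 3 let the family pass, with an adjusted p between 0.0149 and 0.0384 over both forms. The replicate block also let the family pass on 6 arrays (camera, adjusted p = 0.0259). With an estimated correlation the adjusted p was 0.360 on 6 arrays and 0.504 on 5.

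Cytosolic co-chaperones and heat shock genes went both ways. With 6 arrays Chordc1 was lower and the ubiquitin ligase gene Stub1 higher (0.33, SE 0.08) adjusted over the list alone, 0 of 31 passed over all genes, and the list did not pass (camera, adjusted p = 0.495). On 5 arrays Chordc1 fell over all genes, and adjusted over the list alone 4 fell and 2 rose, among them Dnaja1 (−0.46, SE 0.09) and Fkbp4 (−0.48, SE 0.13) downward and Stub1 (0.41, SE 0.07) upward (camera, adjusted p = 0.654). Genes of the unfolded protein response of the endoplasmic reticulum shifted downward as a list. No member of its 27 passed on either count in either form, and the median was −0.06 with 6 arrays (camera, adjusted p = 0.0130, or adjusted p = 0.335 with an estimated correlation) and −0.07 with 5 (camera, adjusted p = 0.0360, or adjusted p = 0.309 with an estimated correlation). The oxidase gene Ero1a differed by −0.28 (SE 0.09) and the calnexin gene Canx by −0.27 (SE 0.09) with 6 arrays. Leaving out wild-type replicate 2 ended this call in both forms (adjusted p = 0.0835 and 0.142), with a median of −0.04 on 5 arrays. On 5 arrays it also ended without the array labelled Hspa4-/- replicate 2 (adjusted p = 0.117), without wild-type replicate 1 (adjusted p = 0.0516) and with camera on ranks (adjusted p = 0.0673). The median was −0.12 on 6 arrays and −0.13 on 5 without the array labelled Hspa4-/- replicate 3, and −0.09 on 6 without wild-type replicate 3.

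Oxidative phosphorylation genes shifted upward with a median of 0.09 over 43 genes with 6 arrays (camera, adjusted p = 7.26e-04, or adjusted p = 0.449 with an estimated correlation). Quantile normalisation lowered this median to 0.056, and the camera call held. On 6 arrays 0 passed on either count, with Uqcrq at 0.44 (SE 0.12) and the cytochrome c gene Cycs, which went the other way, at −0.36 (SE 0.11). On 5 arrays 0 passed over all genes and 5 rose adjusted over the list alone, among them Ndufb8 (0.52, SE 0.10) and Ndufb9 (0.41, SE 0.09), with a median of 0.11 (camera, adjusted p = 7.71e-06, or adjusted p = 0.293 with an estimated correlation). Circadian clock genes had a median of 0.14 over 18 genes with 6 arrays (camera, adjusted p = 0.00927, or adjusted p = 0.449 with an estimated correlation). None passed over all genes, and adjusted over the list alone Per1 (0.39, SE 0.09) and Per3 (0.41, SE 0.11) were higher and Clock (−0.28, SE 0.06) lower. On 5 arrays the median was 0.21, with 0 over all genes and 4 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00124, or adjusted p = 0.362 with an estimated correlation). Leaving out the array labelled Hspa4-/- replicate 2 ended the clock call in both forms (adjusted p = 0.137 and 0.0724), and the median fell to 0.09 on 6 arrays and 0.03 on 5. A filter leaving out the lowest 50% of genes also ended it in both forms (adjusted p = 0.0982 and 0.0547), and quantile normalisation on 6 arrays (adjusted p = 0.0512).

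Proteasome subunits shifted upward by a median of 0.07 over 37 genes with 6 arrays (camera, adjusted p = 0.0453, or adjusted p = 0.670 with an estimated correlation), with 0 passing on either count. Psmb4 differed by 0.24 (SE 0.09) and Psme4 by −0.27 (SE 0.10). On 5 arrays the median was 0.12, with 0 over all genes and only the proteasome activator gene Psme1 (0.43, SE 0.08) higher adjusted over the list alone (camera, adjusted p = 0.00139, or adjusted p = 0.574 with an estimated correlation). Quantile normalisation, a filter leaving out the lowest 50% of genes and leaving out wild-type replicate 3 ended the proteasome call in both forms, with medians of 0.02 on 6 arrays and 0.07 on 5 without that array. On 6 arrays it also ended with the lowest 25% left out, with subtracted medians, and without the array labelled Hspa4-/- replicate 2 (median 0.08) or 3 (median 0.03). The lists of muscle ubiquitin ligases and autophagy and of calcium handling passed in the main test on 5 arrays and not in that on 6. In the former the ubiquitin ligase gene Trim55 (0.64, SE 0.10) rose over all genes and was the only 1 of 26 to do so over the list alone (camera, adjusted p = 0.0360, or adjusted p = 0.657 with an estimated correlation). In the latter Casq1 rose over all genes, and Casq1, the junctophilin gene Jph2 (0.44, SE 0.10), Nfatc2 (0.34, SE 0.09) and Cacna1c (0.26, SE 0.07) rose adjusted over the list alone, out of 34 (camera, adjusted p = 0.0123, or adjusted p = 0.342 with an estimated correlation). Their difference between 6 and 5 arrays was not tested, and quantile normalisation, a low-value filter or leaving out wild-type replicate 3 ended both calls on 5 arrays. The ubiquitin ligase call, with a median of 0.09, also ended without the array labelled Hspa4-/- replicate 2 (median 0.008) or wild-type replicate 1, and its median was 0.05 without wild-type replicate 3, 0.15 without the array labelled Hspa4-/- replicate 3 and 0.17 without wild-type replicate 2. The calcium handling median of 0.07 fell to 0.04 without wild-type replicate 1. With 6 arrays both passed with array weights (adjusted p = 0.00794 and 0.0349) and without wild-type replicate 2 (adjusted p = 1.84e-04 and 0.0197), and the ubiquitin ligase list also with the replicate block and without the array labelled Hspa4-/- replicate 3.

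Markers of other cell types moved beside these groups. Mesothelial markers were lower: with 6 arrays 0 of 11 passed over all genes and 4 were lower adjusted over the list alone, with a median of −0.11 (camera, adjusted p = 7.26e-04, or adjusted p = 0.449 with an estimated correlation). Without the array labelled Hspa4-/- replicate 1, the uroplakin genes Upk1b (log2 difference −0.90, SE 0.13) and Upk3b (−0.78, SE 0.09) fell over all genes, and Muc16 (−0.32) and Lrrn4 (−0.35) also fell adjusted over the list alone. The median was then −0.17 (camera, adjusted p = 1.14e-05, or adjusted p = 0.293 with an estimated correlation), as it was on 6 arrays without wild-type replicate 2. A filter leaving out the lowest 50% of genes ended the mesothelium call on 6 arrays (adjusted p = 0.0888). Macrophage and monocyte markers had a median of −0.07 over 17 genes with 6 arrays, where Mrc1 (−0.50, SE 0.13), Itgam (−0.29, SE 0.08), Lyve1 (−0.30, SE 0.09) and Adgre1 (−0.21, SE 0.07) were lower adjusted over the list alone and 0 over all genes (camera, adjusted p = 0.00279, or adjusted p = 0.335 with an estimated correlation). On 5 arrays the median was −0.08, and Itgam (−0.33) and Csf1r (−0.28) fell adjusted over the list alone with 0 over all genes (camera, adjusted p = 0.0166, or adjusted p = 0.293 with an estimated correlation).

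Endothelial markers were higher, with a median of 0.13 over 15 genes on 6 arrays and Robo4 (0.33, SE 0.07) and Egfl7 (0.33, SE 0.07) higher adjusted over the list alone, 0 over all genes (camera, adjusted p = 0.00103, or adjusted p = 0.360 with an estimated correlation). On 5 arrays the median was 0.15, with Sox17 (0.34, SE 0.09) added over the list alone (camera, adjusted p = 9.71e-04, or adjusted p = 0.377 with an estimated correlation). Smooth muscle and pericyte markers had a median of 0.10 over 14 genes on 6 arrays (camera, adjusted p = 0.00747, or adjusted p = 0.335 with an estimated correlation). Des, which the sarcomere list also holds, and the pericyte receptor gene Pdgfrb (0.29, SE 0.08) were higher adjusted over the list alone, and 0 passed over all genes. On 5 arrays the median was 0.19, with 0 over all genes and 3 higher and 1 lower adjusted over the list alone (camera, adjusted p = 0.00229, or adjusted p = 0.293 with an estimated correlation). Myofibroblast markers passed on 5 arrays and not on 6, a difference that was not tested, with a median of 0.12 over 10 genes and Ccn4 (0.33, SE 0.08) and Postn higher adjusted over the list alone (camera, adjusted p = 0.0106, or adjusted p = 0.293 with an estimated correlation). Leaving out the array labelled Hspa4-/- replicate 3 ended the smooth muscle call on 6 arrays (adjusted p = 0.0591) and the myofibroblast call on 5 (adjusted p = 0.0675). The filter leaving out the lowest 50% of genes ended the smooth muscle call in both forms (adjusted p = 0.0784 and 0.0574) and the endothelial call on 5 arrays (adjusted p = 0.0574). With this filter the myofibroblast median on 5 arrays was 0.36, over the members left in. The smooth muscle median was 0.06 on 6 arrays without the array labelled Hspa4-/- replicate 2 and 0.12 on 5 without replicate 3 of that label, and the endothelial median was 0.23 on 6 arrays without wild-type replicate 2.

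**Figure D3:**
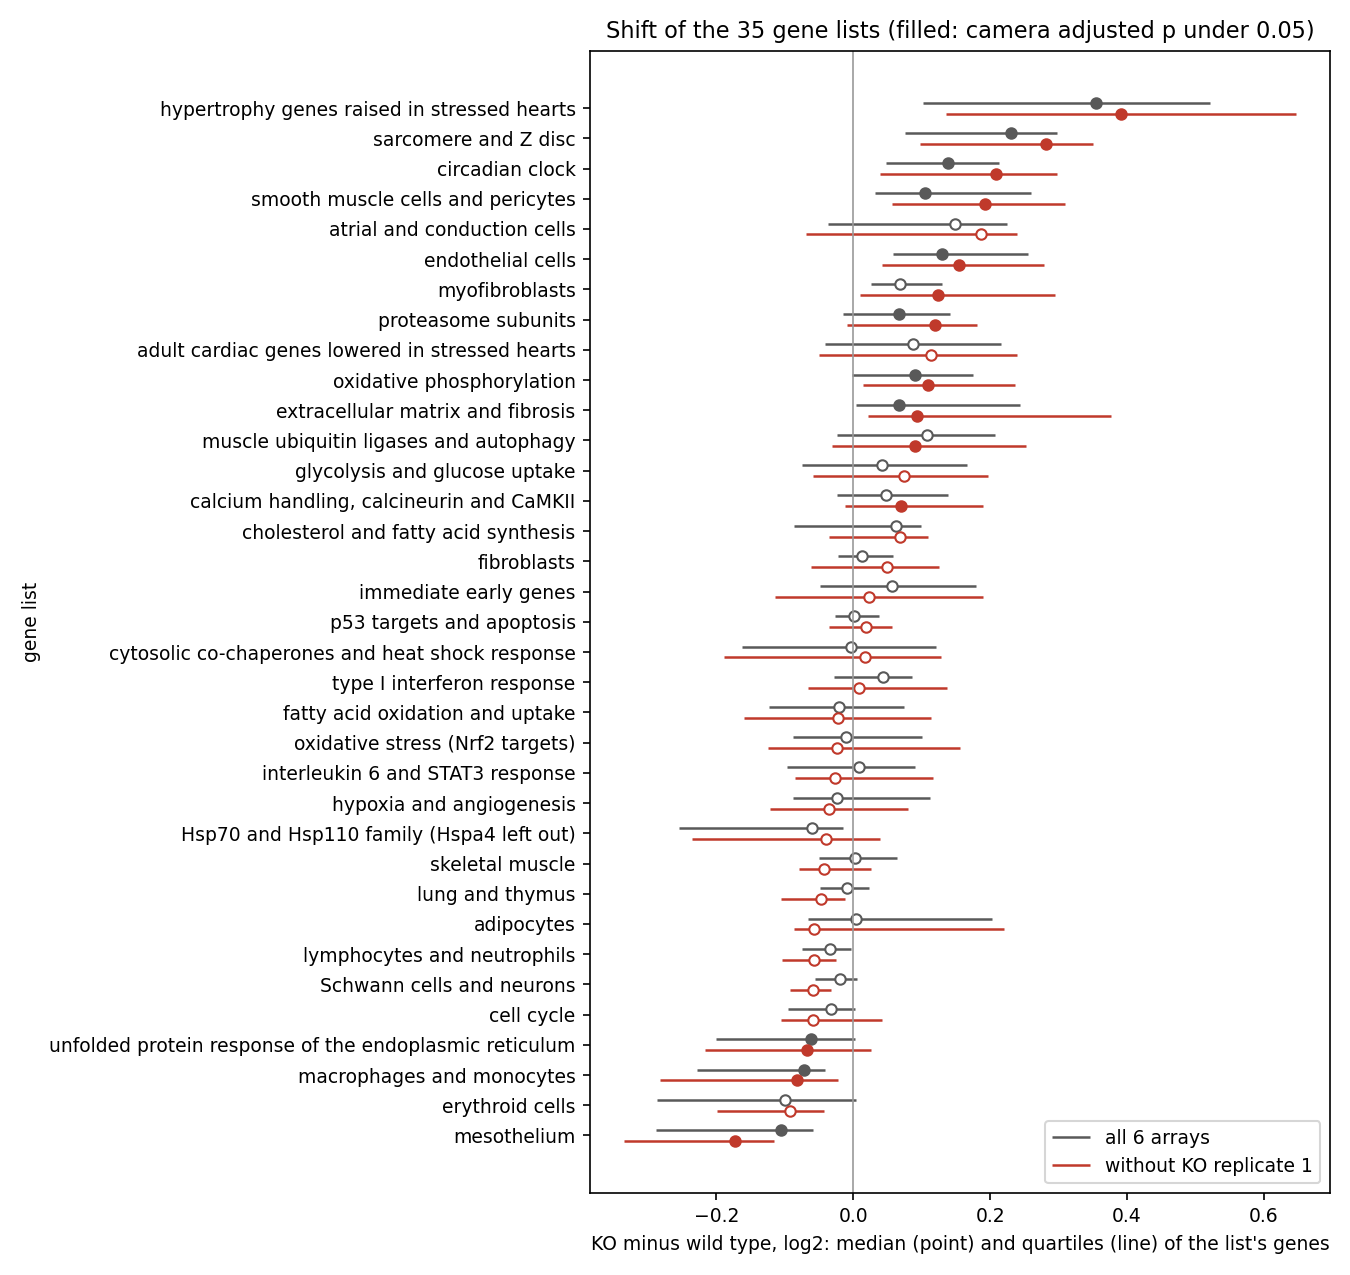
Median (point) and quartiles (line) of the log2 difference, arrays labelled Hspa4-/- minus wild type, for the 35 gene lists with all 6 arrays (grey) and without the array labelled Hspa4-/- replicate 1 (red), filled where camera's adjusted p is under 0.05. The hypertrophy list (0.35 and 0.39) and the sarcomere list (0.23 and 0.28) lie farthest to the right, and the mesothelium list on 5 arrays (−0.17) farthest to the left.

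Of the 35 lists, 11 passed camera with 6 arrays, 8 higher and 3 lower, and 14 without the array labelled Hspa4-/- replicate 1, 11 higher and 3 lower, including the same 11. No list passed with an estimated correlation in either form. On the array labelled Hspa4-/- replicate 1 itself, the median difference from wild type was near 0 for several of these lists: −0.02 for extracellular matrix, −0.002 for the proteasome, 0.005 for oxidative phosphorylation, 0.01 for calcium handling, 0.03 for the clock, −0.01 for mesothelium and −0.04 for myofibroblasts. It was 0.09 for sarcomere genes, 0.07 for muscle ubiquitin ligases, −0.12 for the unfolded protein response, 0.12 for endothelial cells, 0.05 for smooth muscle and −0.09 for macrophages. The lists of adult cardiac genes lowered in stressed hearts, fatty acid oxidation, glycolysis, cell cycle, p53 targets, oxidative stress, interleukin 6 response, type I interferon response, cholesterol and fatty acid synthesis, immediate early genes and hypoxia did not pass in either form. Nor did, in these main tests, the markers of fibroblasts, lymphocytes and neutrophils, erythroid cells, atrial and conduction cells, adipocytes, Schwann cells and neurons, skeletal muscle, or lung and thymus. With the 2 chaperone lists these make 21 lists, whose adjusted p on 5 arrays lay between 0.0734 and 0.896 (camera). Some of them passed under at least 1 alternative, namely fatty acid oxidation, glycolysis, interferon response, cholesterol synthesis, cytosolic co-chaperones and the atrial, erythroid, adipocyte and skeletal muscle markers, beside the Hsp70 and Hsp110 family. Single members still fell or rose over all genes on 5 arrays: Kcnd2 (log2 difference −0.60, SE 0.08) among adult cardiac genes, Egln3 among hypoxia genes, and the apoptosis gene Bcl2l11 (0.52, SE 0.07) among p53 targets. The skeletal muscle list shared its 2 called members, Acta1 and Casq1, with the lists above, and the atrial list shared Nppa.

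Genes near Hspa4 on its chromosome did not stand apart in the main test of 6 arrays. Of the 296 measured genes within 10 Mb of it, 0 passed (limma), and their median log2 difference was 0.0026, at the 95.2 percentile of 10000 random gene sets matched on mean expression. Without the array labelled Hspa4-/- replicate 1, Sec24a, Usp22 (0.50, SE 0.08) and Slc47a1 (0.52, SE 0.08) passed among them, and the median was −0.02, at the 49.3 percentile. These 3 genes are named because they are few, after their values were seen. On 6 arrays the median lay beyond the threshold of the random sets in 2 settings, with a low-value filter that left out the lowest 25% of genes (97.81 percentile) and without the array labelled Hspa4-/- replicate 3 (97.7 percentile).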

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

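Probe sets without a gene name stood outside the report's comparisons. When all 21225 probe sets were tested on the 5 arrays left without the array labelled Hspa4-/- replicate 1, 7 of the 986 unnamed probe sets passed (limma), 1 higher and 6 lower than wild type. With all 6 arrays 0 of them passed, as did 0 of all 21225, where 2368 had an unadjusted p under 0.05. Their genes are not analysed here, and no explanation was tested.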

How the results depend on the processing

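No result past its threshold turned its direction under any alternative that was run. The alternatives on the 5 arrays left without the array labelled Hspa4-/- replicate 1 were chosen after seeing the data. With all 6 arrays, where 0 genes passed, low-value filters let 2 and 2 pass (Chordc1 and Leng8 both times), and array weights gave 115. The filters lowered the number of genes tested, and the model was fitted again on the genes left. Leaving out each array in turn gave from 0 to 112 genes: 112 without wild-type replicate 2, 89 without the array labelled Hspa4-/- replicate 1 and 0 otherwise. Quantile normalisation, subtracted medians, trend and robust settings, all probe sets and the 1.5-fold threshold left the count at 0. On 5 arrays the 89 genes became 157 and 160 with the low-value filters, 36 with subtracted medians, 321 with array weights and 55 with the 1.5-fold threshold. Leaving out another array gave from 2 to 875 genes, 875 without wild-type replicate 2 and 2 without wild-type replicate 3, namely Hspa4 and Kcne1. Where 1 array of a label remained, its spread was taken to equal that of wild type. Without wild-type replicate 1, 6 genes passed: Hspa4, Kcne1, Mylk4, Maob, Egln3 and Hsph1. The cause of these changes in the counts was not tested. Array weights moved Hspa4 to −2.545 (limma, adjusted p = 0.0488), and leaving out 1 array gave from −2.888 to −1.537, past the threshold only without the array labelled Hspa4-/- replicate 1. Camera with an estimated correlation and fry called 0 and 0 lists on 6 arrays, and 0 and 1 on 5. Under the other settings the lists called on 6 arrays kept their call in 5 of 11 cases, namely hypertrophy, sarcomere, oxidative phosphorylation, endothelial cells and macrophages. On 5 arrays 5 of 14 did, with mesothelium in place of endothelial cells. The median over genes near Hspa4 on its chromosome was 0.02015 with the lowest 25% of genes left out, −0.001322 with subtracted medians and −0.0003184 with array weights, and from −0.01743 to 0.01318 with 1 array left out. Across the lists, 467 of 560 comparisons on 6 arrays and 429 of 525 on 5 kept direction and side of the threshold, as did 1111 of 1180 and 1087 of 1269 for named genes. These shares also count lists and genes that stayed without a call, and the main test on 6 arrays called no gene. Of the 29 named genes other than Hspa4 called on 5 arrays, only Kcne1 kept its call in every setting. The mean over probe sets and the pseudocounts were not run, having nothing to act on.

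Equal replicate numbers in both groups did not pair the arrays: the deviations of arrays with the same number correlated at −0.17, 0.09 and −0.25 across genes. With the number as a replicate block, 2 genes passed on 6 arrays (Chordc1 and Lgi1), and 134 on 5, sharing 73 with the 89. Not every array correlated best with its own number.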

Other observations

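Of the tests in this part, only the count of neighbouring gene pairs and the splits of the 6 arrays were set before their result was seen. The genes of the next paragraphs that the rule for named genes left out were chosen after their values were seen.

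Kcnd2 and Kcnj3, single potassium channel genes, fell on the 5 arrays left without the array labelled Hspa4-/- replicate 1, on which Kcne1 rose. No list of channel genes was tested. Kcnd2, which carries the transient outward potassium current, fell by 0.60 on the log2 scale (SE 0.08; limma, adjusted p = 0.0237). Kcnj3, a subunit of the acetylcholine-activated potassium channel, fell by 0.55 (SE 0.08; limma, adjusted p = 0.0310). Kcnip2, a partner of Kcnd2 channels, was higher by 0.47 (SE 0.15) while the pacemaker channel gene Hcn4 with −0.36 (SE 0.07) and Kcnv2 with −0.57 (SE 0.12; limma, adjusted p = 0.0877) were lower. These 3 passed adjusted over their lists alone and not over all genes. Outside the channels, Bves, a membrane protein gene of the Popeye family active in heart muscle, rose by 0.60 (SE 0.07; limma, adjusted p = 0.0225), and the cardiac transcription factor gene Gata6 by 0.63 (SE 0.10; limma, adjusted p = 0.0402).

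H2-Ab1 and Tap1, genes of antigen presentation, rose on the same 5 arrays. H2-Ab1, a chain of MHC class II, rose by 0.72 (SE 0.11; limma, adjusted p = 0.0402), and the peptide transporter gene Tap1 rose by 0.56 (SE 0.07; limma, adjusted p = 0.0237). They lie 0.0757 Mb apart on chromosome 17, so they do not count as 2 independent genes. Other genes of the class II pathway did not pass over all genes: H2-Aa at 0.76 (SE 0.15; limma, adjusted p = 0.0657), Cd74 at 0.74 (SE 0.16; limma, adjusted p = 0.0883, or 0.0271 over its list alone) and H2-Eb1 at 0.55 (SE 0.13; limma, adjusted p = 0.108). On the array labelled Hspa4-/- replicate 1, H2-Ab1 differed by −0.23 and H2-Aa by −0.56 from the wild-type mean.

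The array labelled Hspa4-/- replicate 1 had Hspa4 near wild type and high Xist. Xist lay 1.99 above the highest other array on the log2 scale, which argues against a wild-type male heart under a wrong label. Eif2s3y at 76.77% of the mean of the other arrays is consistent with RNA of male and female hearts on 1 array, a candidate explanation found from these values. A mix of Hspa4-/- and wild-type RNA was read from the 88 other called genes, which put the array 24.9% of the way to the other arrays labelled Hspa4-/-. The 95% interval, from resampling these genes, was 18.7% to 35.2%. All the genes come from the same arrays, so it can be too narrow. Hspa4 gave 18.3%, just outside that interval, with 11.6% to 28.5% over pairs of arrays, a range that overlaps it. Wild-type replicate 2 stood at 41.4% by the same measure on 88 genes chosen without it, so such a mix and ordinary spread between hearts cannot be told apart.

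The 89 genes that changed without that array could reflect unequal spread between arrays, chromosome segments that differ between the groups, or the loss of Hspa4. Quantile normalisation left 94 genes, 79 of them among the 89, which argues against unequal spread as the whole cause. Subtracting array medians left only 36, so a part played by differences between the arrays' distributions stays open. There were 6 pairs of called genes within 2 Mb of each other, while random gene sets had a median of 10 and a 95th percentile of 17. This argues against many such segments as the whole cause. Hspa4 itself was left out of the count, which could not show a single segment, such as one holding Hspa4 and Sec24a, within 10 Mb of it. A single segment stays open for each pair: Usp22 and Slc47a1, both within 10 Mb of Hspa4, H2-Ab1 and Tap1, Nppa and Fv1 (0.132 Mb apart), Gnao1 and Ces1d (0.644 Mb), Kcne1 and Tmem50b (0.771 Mb), and C7 and Dab2 (1.31 Mb). The real split was the only 1 of 10 to reach 89 genes, but wild-type replicates 1 and 3 against the rest gave 85, a structure in which wild-type replicate 2 stands with the arrays labelled Hspa4-/-, and 10 splits are too few for a share under 0.05. That other split exceeded the real one in genes with an unadjusted p under 0.05, 3641 against 3018, and in lists, 16 against 14. The limit of 10 splits also holds with 6 arrays, where 10 of 10 splits gave 0 genes as the real one did, and 4 of 10 gave at least its 11 lists, the highest other 13.

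Hsph1 and Chordc1, both partners of cytosolic chaperones, fell together on 5 arrays. Signal of the Hspa4 transcript on probes of its relatives could lower Hsph1 when Hspa4 is lost. The relative Hspa4l differed by −0.2357 while Hsph1 fell by 1.00 on the log2 scale. Probes of the 2 relatives can differ in how much of such signal they take up, so this signal and a difference of Hsph1 by genotype cannot be told apart. Chordc1 is no relative, so its fall says nothing about Hsph1. On the array labelled Hspa4-/- replicate 1, where Hspa4 was near wild type, Chordc1 still differed by −0.66, against −0.82 on the 5 arrays. Hsph1 differed there by −0.32, and Hspa4l by −0.29, against −0.2357 for Hspa4l on the 5 arrays. On that 1 array Chordc1 and Hspa4l thus went with the label and not with the Hspa4 level. Hspa4l is therefore a poor measure of such stray signal, and the test with it decides nothing. A difference by genotype stays open as a hypothesis for both Hsph1 and Chordc1. Other differences that go with the labels, biological or technical, were not tested for them.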
